A study of Gossypium hirsutum with 51 samples.

How the data were processed

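The series measured transcript levels in upland cotton (Gossypium hirsutum) ovules by hybridising total RNA to cDNA arrays with 2 dyes, Cy5 and Cy3. Ovules came from wild type and from the fl mutant at ages given in days post anthesis, the day the flower opens counting as 0. Per the labels, 8 comparisons were each hybridised as 3 sets of an array and its dye swap, which gave 6 arrays per comparison, and 3 further arrays carried wild-type RNA of age +3 in both channels. The deposited design text calls the samples biologically independent, so a set was treated as 1 replicate, and its 2 arrays, which hold the same pair of RNAs with exchanged dyes, were averaged. Each group, dye and set number was taken from the labels.

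The authors deposited 1 table of log2 ratios with 11706 rows and 51 arrays, of which 11682 rows are cDNA clones, 11 are spots listed under gene-like names and 13 are controls. The unit was found from the values. Raised to the power of 2, the control rows of every array are whole multiples of 0.0001 within a tolerance of 0.02 of a step. The clone rows of 10 arrays are such multiples too, while those of the other 41 arrays were normalized by the authors by a method not given in the sources used here. Array medians over clones ran from -0.15 to 0.11 in the 41 normalized arrays and from -0.52 to 0.47 in the other 10. The 10 are the self-to-self arrays, the comparison of -3 with +3 and 1 array of +10 against +3. The 11 named spots are on the unnormalized scale on every array.

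Brightness per spot is not in the table used here, so no filter on dim spots was possible, and the number of arrays limits the precision. An exact 0 was treated as not measured. In the 1 array found in both a normalized and an unnormalized version, 1980 clones are exact zeros in the former and missing in the latter. Normalized arrays hold between 20 and 3806 exact zeros against at most 5 elsewhere. An array measured between 7639 and 11681 clones, with a median of 11053.

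The direction of the ratios is not stated in the labels and is called likely here. A control spot named HEX read from -11.7 to -7.16 on the 23 forward arrays with a value and from 5.83 to 12.1 on the 23 dye swaps. If HEX marks a dye seen in the Cy3 channel, the control rows are the first RNA of the title over the second, with the swaps already turned. Self-to-self set 2, for which the design text lists the dyes in reverse order, was turned, and its HEX value was 8.25 against -9.04 and -8.59 in sets 1 and 3. The clone rows of wild type against fl at +3 were turned by the analysis after their values had been seen. Their probe-specific dye effect, the difference of forward and swapped array divided by 2, in which the RNA difference cancels, correlated with the self-to-self arrays at -0.57 to -0.40 across clones in the 3 sets. In the 21 sets of the other comparisons the same correlation ran from -0.06 to 0.69 and lay below 0 in 1. That was set 3 of wild type against fl at +10, whose sets 1 and 2 stood at 0.19 and 0.39. The sign of wild type against fl at +3 is not settled by the labels, and values with the deposited sign at +3 are given beside the turned ones.

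The array of +5 against +3 in set 3 with forward dyes and that of +10 against +3 in set 2 with forward dyes carry the same control values. All 19 of 19 control values measured in both are equal to 6 decimals, where no other of the 1275 pairs of arrays shares more than 1. Because the labels give this array 2 ages, it was left out of both comparisons before its effect on the counts was known. Both comparisons then rest on 2 complete sets, a departure from the 3 sets planned, and results with the array kept are given where they differ.

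Differences were tested with limma 3.58.1 in R 4.3.3. One group-means model was fitted to all 8 comparisons, with lmFit, empirical Bayes moderation and Benjamini-Hochberg adjustment within each contrast, and probes with an adjusted p under 0.05 were called changed. A probe was tested in a comparison when at least 2 sets had both arrays measured. Signs were set so that each age was compared with +3 of wild type and wild type with fl. The prior had 6.12 degrees of freedom and an SD of 0.184 (log2). Contrasts of comparisons gave the change of the genotype difference with age, the change of fl from +3 to +10, which no array measured directly, and adjacent ages through +3. An F test covered the 6 age coefficients.

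Tested on simulated data with the spread of the real probes, the same fit recovered 98.5% of 67 probes changed by 1 on the log2 scale and 65.7% of 67 changed by 0.5 for wild type against fl at +10, among 9210 probes, with 10 of 9010 unchanged probes called. For +10 against +3, with 2 sets and 10317 probes, it recovered 100% and 49.3%, with 6 of 10117 unchanged probes called. The simulation drew all comparisons of a probe from 1 normal spread, without offsets of arrays or plates. It therefore cannot show how the fit behaves where the real sets depart from that.

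The table used here does not pair clones with genes. None of the 11682 clone names is among the gene identifiers of the RefSeq table for assembly Gossypium_hirsutum_v2.1, and 3 of the 11 named spots (ACT1, ACT2 and TUB1) are listed there as symbols or synonyms, without proof that the spots carry those sequences. The 28 gene lists fixed before the data were examined could therefore not be tested. By the rule fixed at the same time, the clones named in each comparison are the 2 with the largest positive and the 2 with the largest negative log2 ratio among changed clones, with one sign in every measured set for the 8 direct comparisons. No condition on single sets was put on the change of the genotype difference. The 11 named spots were added because the table names them, and groups of clones were formed by genotype difference after the data had been examined. Such groups were tested with limma's cameraPR, with a preset correlation of 0.01 and with the correlation estimated from residuals, and Benjamini-Hochberg adjustment over 53 tests.

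Alternatives fixed before the data were examined were centring, scaling, a dye term, a random block for sets, either dye orientation alone, stricter and looser rules on missing spots, fits of each comparison alone, robust moderation, a fixed replicate block, each set left out, stricter thresholds and a one-sample test of each probe without shared spread. Keeping exact zeros, keeping the shared array and keeping the deposited sign at +3 were added after seeing the data. The random block used statmod 1.5.0, and the figures were drawn with matplotlib 3.10.9.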

Results

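Transcript levels were compared on 51 cDNA arrays of upland cotton ovules, the organs from whose surface cells cotton fibres grow. Wild-type ovules of ages -3, 0, +5, +10, +15 and +20 days post anthesis were each compared with wild-type ovules of age +3. Wild type was compared with the fl mutant at +3 and at +10. Each comparison comprised 3 sets of an array and its dye swap, and 3 self-to-self arrays carried +3 wild-type RNA in both channels. Values are log2 ratios, and n is the number of sets with both arrays measured. The comparisons with +5 and +10 had n = 2, because 1 array occurs under both and was left out. Ratio directions are likely rather than stated, on the basis of a control spot, and the clone signs of wild type against fl at +3 were turned.

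At +10, 1242 probes differed at least 2-fold between wild type and fl, against 502 at +3. With differences of any size, 6092 of 9210 probes tested at +10 differed, 2430 higher and 3662 lower in wild type. Among those at least 2-fold apart the balance was the other way, with 878 higher and 364 lower. If all ratios run the other way, the counts of higher and lower exchange places. Clone CM005F03 was 46.2-fold higher in wild type, at 5.53 ± 1.49 (log2, SD, n = 3; limma adjusted p = 1.19e-11), and CM123E12 was 31.6-fold higher at 4.98 ± 1.15 (SD, n = 3). Clone CM015H12 was 19.7-fold lower at -4.30 ± 1.69 (SD, n = 3), and CM050F11 was 8.54-fold lower at -3.09 ± 0.21 (SD, n = 3; adjusted p = 2.58e-15). The sets of CM015H12 ran from -6.24 to -3.16, and apart from this comparison it was tested only at 0 against +3. Here and below, the limma adjusted p rests on 1 spread per probe taken from all comparisons in which the probe was tested. It does not rest on the SD over sets printed beside it. For CM005F03 the SE from that spread was 0.34. Centring each array on its clone median moved the median probe by 0.13, which turned the split to 3112 higher and 2800 lower. Changes at +10 smaller than that shift therefore have no settled direction. Clones on plates from 80 up, by the plate numbers in their names, had a median of -0.33, against -0.0092 on the other plates. If that gap is an offset, changes there up to its size have no settled direction either.

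At +3, 4476 of 10106 probes differed between wild type and fl, 1931 higher and 2545 lower in wild type. With the clone sign turned, 412 were at least 2-fold higher and 90 lower, and with the deposited sign 93 higher and 409 lower. Centring turned the split of all changed probes to 2473 higher and 2333 lower. Clone CM005F03 was also among the largest here, 19.4-fold higher in wild type at 4.28 ± 0.82 (SD, n = 3; limma adjusted p = 2.00e-09). Clone CM099E09 was 16.0-fold higher at 4.003 ± 0.20 (SD, n = 3). Clones CM024F10 and CM032E03 were lower in wild type, at -2.21 ± 0.12 and -2.06 ± 0.12 (SD, n = 3 each). With the deposited sign, the split becomes 2553 higher and 1923 lower and each of these 4 clones changes direction.

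The genotype difference was shared between the ages for many probes. Of 8833 probes tested at both, 1216 were higher in wild type at +3 and +10, where independent lists would share 480, and 1261 were lower at both, where independent lists would share 906. With a minimum of 2-fold, 369 were higher at both ages against 38.2 for independent lists. Across probes, which are not independent replicates, the differences at the 2 ages correlated with a Pearson r of 0.66 and a Spearman rho of 0.44. The 2 comparisons name no RNA in common. With the deposited sign at +3, the Pearson r across clones is -0.66, 275 probes are higher at both ages, and 9 are at least 2-fold higher at both, against 6.06 for independent lists.

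**Figure D1:**
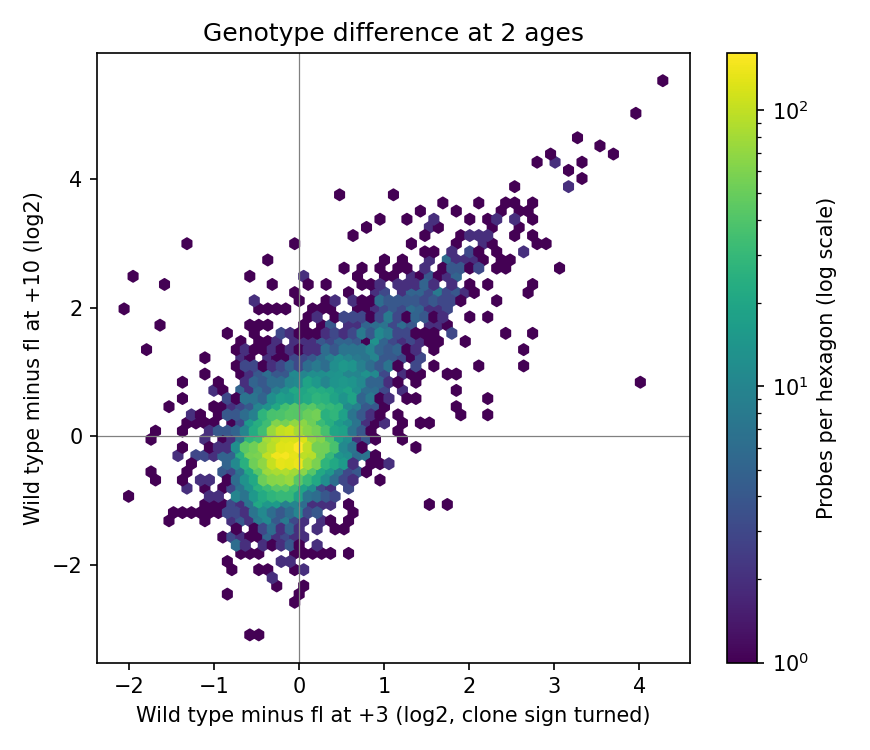
Wild type minus fl at +3 (x axis, log2, clone sign turned) against the same difference at +10 (y axis, log2), with the number of probes per hexagon as colour on a log scale. The 8833 probes tested at both ages correlate at 0.66, with a tail of probes higher in wild type at both.

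The genotype difference, taken with its sign, changed with age for 3975 of 8833 probes, 1894 towards wild type and 2081 towards fl at +10. Clone CM025C03 went from -1.95 ± 0.28 (SE) at +3 to 2.42 ± 0.28 (SE) at +10, a change of 4.37 (limma adjusted p = 6.20e-08). Clone CM027E10 went from -1.34 ± 0.18 to 2.95 ± 0.18 (SE). Clone CM099E09 fell from 4.003 ± 0.15 to 0.88 ± 0.15 (SE), and CM101H12 from 1.74 ± 0.11 to -1.07 ± 0.11 (SE). Each SE rests on 1 spread per probe taken from all comparisons, not on the spread at that age. The SD over sets of CM025C03 was 0.22 at +3 but 1.37 at +10 (n = 3 each). Its sets at +10 ran from 1.24 to 3.92. At +3 and +10 the SDs were 0.23 and 0.22 for CM027E10 and 0.20 and 0.094 for CM099E09. For CM101H12 they were 0.038 and 0.072. With the deposited sign at +3, 5780 probes change, of which 2821 are the same probes, and the change of CM025C03 is 0.47 with an adjusted p of 0.302. The changes of CM027E10, CM099E09 and CM101H12 are then 1.61, 4.88 and 0.68, of which the last 2 have the opposite sign. The count was 2519 without set 1 and 2445 without set 3. Centring the arrays gave 2516 probes towards wild type and 1908 towards fl.

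Between +3 and +10, the fl mutant changed at 3148 of 8709 probes when its change was derived from 3 comparisons, 1652 higher and 1496 lower at +10. Centring turned this split to 1706 higher and 1945 lower. Of 515 probes at least 2-fold higher at +10 than at +3 in wild type and with a derived fl value, 250 also rose in fl, 18 fell and the median was 1.19 in wild type and 0.60 in fl. The genotype difference, wild type minus fl with its sign, increased for 300 of these and decreased for 66. Of 279 probes at least 2-fold lower in wild type, 219 fell in fl, and the medians were -1.17 and -1.02. The probes were selected on the wild-type change, whose arrays also enter the derived fl value, so an error there moves both the same way. In 20 simulations with fl unchanged and the errors of the 3 comparisons drawn independently, at most 10 probes of the first group rose in fl, with a median of 0.06, and at most 7 of the second fell, with a median of -0.07. With the deposited sign at +3, 4404 probes change in fl, 1871 of them the same. Of the 515, 190 then rise and 216 fall in fl with a median of -0.01, and the genotype difference increases for 363 and decreases for 72. Of the 279, 172 fall in fl, with a median of -0.75. The count was 1320 without set 1 and 1496 without set 3.

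Before and at flowering, ovules differed from +3 mainly by lower levels of strongly changed probes. With the direction of all ratios turned, these would be higher levels. At -3, 4824 of 10704 probes changed, 2143 higher and 2681 lower than at +3, and 103 were higher and 576 lower by at least 2-fold. Clone CM005F03 was 42.7-fold lower at -3 than at +3, at -5.42 ± 0.53 (SD, n = 3; limma adjusted p = 3.97e-11). Clone CM123E12 was 23.8-fold lower at -4.57 ± 0.04 (SD, n = 3). The largest increases were CM003E03 at 2.69 ± 0.40 and CM027H12 at 2.55 ± 0.40 (SD, n = 3 each). Without set 1, 3077 probes changed at -3.

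At 0, 3342 of 11675 probes changed, 1683 higher and 1659 lower, with 114 higher and 269 lower by at least 2-fold. Clone CM005H11 was 20.9-fold lower at -4.39 ± 0.24 and CM025A04 was 17.1-fold lower at -4.10 ± 0.21 (SD, n = 3 each; limma adjusted p = 4.36e-14 and 3.07e-12). Clones CM105E12 and CM038H03 were higher, at 3.13 ± 0.72 and 2.96 ± 0.02 (SD, n = 3 each). Each of these 4 had one sign in the 3 sets. A fit of this comparison alone called 6446 probes and scaling of the arrays called 6770, and the cause of the difference was not tested. The main fit takes 1 spread per probe from all comparisons. At 0, the SD over sets of each of the 11 named spots lay below its SE from that spread. The values ran from 0.01 against 0.14 for ACT2 to 0.15 against 0.16 for USP1, while CM105E12 had 0.72 against 0.23. Clone CM105E12 was tested in no other comparison, so its SE rests on its sets at 0 and the prior. Centring turned the split to 1607 higher and 2085 lower. Leaving out set 1 gave 2026 probes, set 2 gave 2201 and set 3 gave 2068.

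At +5, 5394 of 9633 probes changed, 2583 higher and 2811 lower, and at least 2-fold changes were 483 higher and 266 lower. Centring turned the split to 2947 higher and 2829 lower. Clone CM006E07 rose 12.4-fold, at 3.64 ± 0.06, and CM019E04 rose 9.66-fold, at 3.27 ± 0.04 (SD, n = 2 each; limma adjusted p = 1.54e-05 and 5.49e-10). Clones CM123H11 and CM036F02 were lower, at -3.60 ± 0.32 and -3.30 ± 0.92 (SD, n = 2 each).

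At +10, 6094 of 10317 probes changed against +3, 2975 higher and 3119 lower, with 639 higher and 385 lower by at least 2-fold. Centring turned the split to 3337 higher and 3150 lower. Clone CM013A08 rose 33.1-fold at 5.05 ± 0.03 and CM006E07 rose 19.9-fold at 4.32 ± 0.23 (SD, n = 2 each; limma adjusted p = 4.07e-08 and 2.28e-06). Clones CM001C04 and CM078G11 fell, at -3.51 ± 0.62 and -3.48 ± 0.14 (SD, n = 2 each). With the shared array kept in both comparisons, 6105 probes changed at +5 and 6973 at +10.

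At +15, 7273 of 10696 probes changed, 3364 higher and 3909 lower, with 838 higher and 786 lower by at least 2-fold. Clone CM013A08 stood 62.4-fold above +3, at 5.96 ± 1.18, and CM041D09 57.8-fold above it, at 5.85 ± 2.19 (SD, n = 3 each; limma adjusted p = 8.33e-11 and 2.54e-07). Clone CM086E04 was 90.3-fold lower at -6.50 ± 1.75 and CM099E09 was 47.7-fold lower at -5.58 ± 0.38 (SD, n = 3 each). At +20, 7272 of 10491 probes changed, 3517 higher and 3755 lower, with 827 higher and 766 lower by at least 2-fold. The rule named the same 4 clones, CM041D09 at 5.14 ± 0.50, CM013A08 at 5.11 ± 0.32, CM086E04 at -5.82 ± 0.40 and CM099E09 at -5.66 ± 0.35 (SD, n = 3 each).

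**Figure D2:**
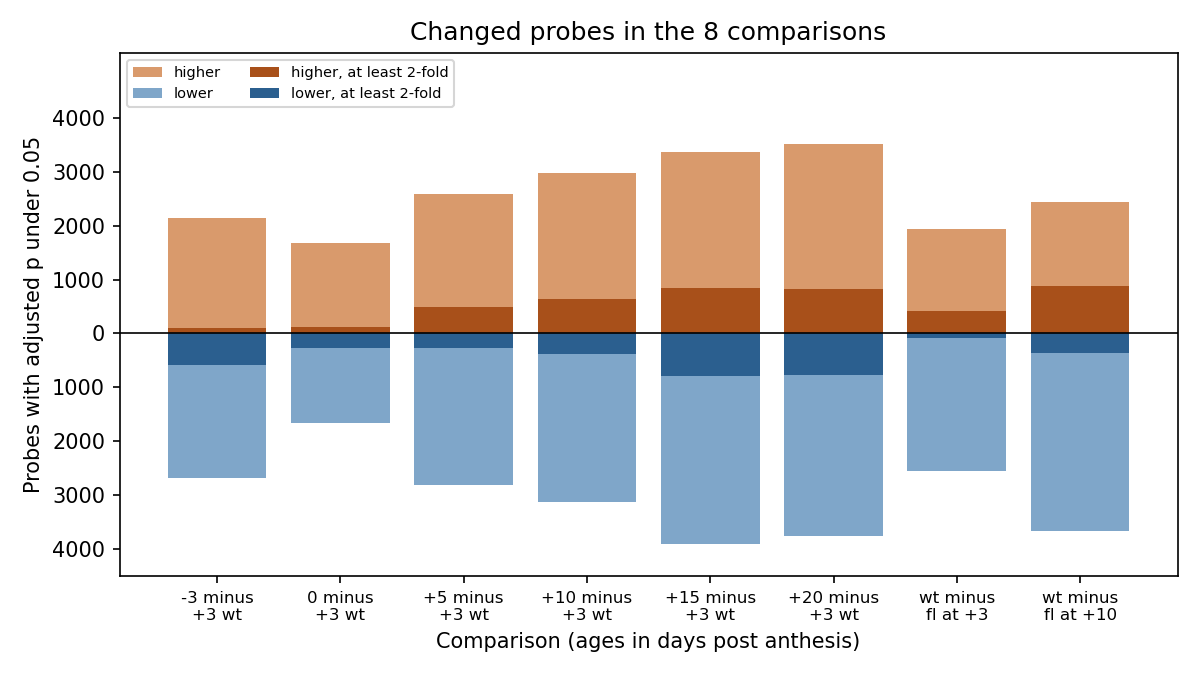
Number of probes with an adjusted p under 0.05 in each comparison (y axis, probes higher above 0 and lower below 0), with darker parts for those at least 2-fold apart. The bars are widest at +15 and +20, with 7273 and 7272 probes, and at least 2-fold differences between wild type and fl lie mostly above 0 at +10, and at +3 with the clone sign turned as drawn.

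Over the 7 wild-type ages, 8311 of 9161 probes measured in all 6 age comparisons changed by limma's F test, and 4097 of these varied at least 2-fold. Of the 4097, 893 were highest at 0, 682 at +10, 664 at -3, 632 at +5, 560 at +20, 512 at +15 and 154 at +3. The value at +3 is 0 by construction and carries no error of its own, which makes an extreme at +3 less frequent. The lowest value lay at -3 in 1322, at +20 in 720, at +15 in 522, at +5 in 458, at 0 in 455, at +10 in 405 and at +3 in 215. A total of 1057 probes were highest at +5 or +10 and lowest at -3 or 0, and 636 had the opposite course. With the direction of all ratios turned, highest and lowest exchange places, as do these 2 counts. Without set 1 in each comparison, 5511 probes changed by the F test.

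Ages were also compared indirectly through +3. From +10 to +15, 3121 of 10088 probes changed, 1482 higher and 1639 lower at +15. From -3 to 0, 2051 of 10688 probes changed, 1467 higher and 584 lower, and the split was 1401 against 935 after centring and 1889 against 1816 after scaling the arrays. From +15 to +20, 817 of 10257 probes changed, 403 higher and 414 lower, and after scaling 145 against 305. From +5 to +10, 576 of 9439 changed, 387 higher and 189 lower, and 852 with the shared array kept at +10 only. Leaving out 1 set gave between 171 and 255 probes from +5 to +10, 292 to 420 from +15 to +20, 902 to 2010 from -3 to 0 and 1617 to 2573 from +10 to +15.

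Most of the 878 probes at least 2-fold higher in wild type than in fl at +10 shared a course in wild type. At -3, 715 of the 857 tested were lower than at +3 and 25 were higher, with a median of -1.12. At 0, 686 of 878 were lower, with a median of -0.71. At +5, 706 of 853 were higher, with a median of 0.75, and at +10, 749 of 874 were higher, with a median of 0.87. With an estimated correlation between probes of 0.197, the set stood apart from the other probes at -3 (cameraPR adjusted p = 5.02e-07), at 0 (adjusted p = 1.10e-06), at +5 (adjusted p = 0.00332) and at +10 (adjusted p = 0.00394). At +15 and +20 the medians were 0.35 and 0.41, and the calls made with the preset correlation were lost with the estimated one (adjusted p = 0.527 and 0.434). At +3, 686 of 837 were higher in wild type than in fl, with a median of 0.92. Under the deposited sign 684 are lower there and the median is -0.91. With the sign turned, 151 of the 878 were not called higher at +3, with medians of -0.16 at -3 and -0.19 at 0. The 369 at least 2-fold higher at both ages had -1.64 and -1.08. The +3 wild-type RNA that split these groups also enters those medians. Under the deposited sign 795 are not called higher, with medians of -1.17 and -0.74. The +10 wild-type RNA by which the 878 probes were chosen also enters their values at +10 against +3.

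The 364 probes at least 2-fold lower in wild type than in fl at +10 moved less at the early ages. At -3, 117 of the 332 tested were higher than at +3 and 37 were lower, and at 0, 128 of 364 were higher and 18 were lower, with medians of 0.20 at both. The calls made with the preset correlation at these ages (cameraPR adjusted p = 5.73e-05 and 1.16e-08) were lost with the estimated one (adjusted p = 0.525 and 0.361). At +15, 201 of the 349 tested were higher than at +3 and 75 were lower, with a median of 0.49, and at +20 the figures were 194, 84 and 0.41. The estimated correlation of 0.252 left no call for this set at +15 or +20 (cameraPR adjusted p = 0.259 and 0.295). At +3, 157 of 307 were lower in wild type than in fl and 10 were higher, with an adjusted p of 0.413 for the set with an estimated correlation. Under the deposited sign 157 are higher and 10 lower.

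**Figure D3:**
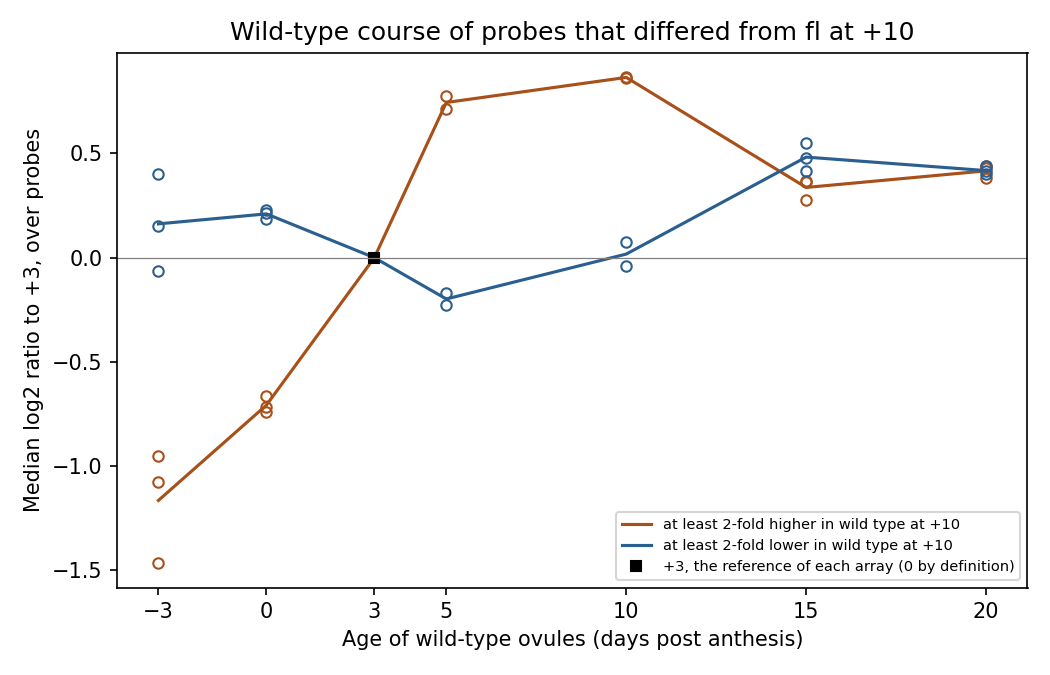
Median log2 ratio to +3 wild type (y axis) against age in days post anthesis (x axis) for the 878 probes at least 2-fold higher and the 364 at least 2-fold lower in wild type than in fl at +10; open circles are sets and lines join their means. The higher group lies below 0 at -3 and 0 and above 0 from +5 on.

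Probes higher in wild type than in fl at +10 overlapped with those higher at +10 than at +3. Of 9007 probes tested in both, 1581 were higher in both, where independent lists would share 743, and 1544 were lower in both, where independent lists would share 1040. With at least 2-fold differences the overlap was 326 against 58.8. Both comparisons contain +10 wild-type RNA, and its part in the excess cannot be separated here. In 20 simulations of unchanged groups with a shared +10 sample no probe was called in both, and the simulated covariance was 0.00664 against 0.226 observed. With all groups unchanged, few probes can be called in either list. The simulated count of 0 therefore cannot show how much of the overlap the shared RNA adds. The observed Pearson r across probes was 0.46 and the simulated one 0.41.

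Among the 11 spots listed under gene-like names, ACT1, SDH and TUB1 were lower at -3 and 0 and higher at +5 and +10 than at +3. ACT2 and TUB2 were also higher at +5 and +10 but did not share the early part of this course. ACT2 was at -0.14 at -3 and -0.08 at 0, and TUB2 at -0.21 and 0.16, none of them called. Between wild type and fl at +10 they were at 0.09 and -0.07, not called either. ACT1, a name the RefSeq table gives to an actin gene, was higher in wild type than in fl by 1.95 ± 0.18 at +3 and by 1.55 ± 0.45 at +10 (log2, SD, n = 3 each; limma adjusted p = 2.04e-09 and 2.19e-08). It was lower at 0 than at +3, at -1.29 ± 0.02 (SD, n = 3), and higher at +10, at 1.03 ± 0.50 (SD, n = 2), but lower again at +15, at -0.38 ± 0.29 (SD, n = 3; adjusted p = 0.0296). SDH was higher in wild type than in fl by 2.04 ± 0.40 at +3 and by 1.81 ± 0.65 at +10 (SD, n = 3 each). TUB1 rose from -1.74 ± 0.12 at -3 (SD, n = 3) to 1.86 ± 0.19 at +10 (SD, n = 2), both against +3. Its excess in wild type over fl was 1.27 ± 0.18 at +3 and 0.52 ± 0.08 at +10 (SD, n = 3 each), a change of -0.75 (adjusted p = 0.000303). USP1 was higher in wild type at +3, by 0.90 ± 0.11, and lower at +10, at -0.69 ± 0.23 (SD, n = 3 each), a change of -1.59 (adjusted p = 1.79e-06). These spots were not normalized, and at +3 their median in wild type over fl was 0.66, with 8 of 11 higher and 0 lower, against -0.0026 at +10. The change of TUB1 is close to that shared shift and is not read as its own, while that of USP1 exceeds it. With forward arrays alone the excess of TUB1 at +10 was 0.32 and did not pass (adjusted p = 0.0897). The named spots were not turned at +3. Were their direction there the opposite, their differences from fl at +3 would change sign, and the changes from +3 to +10 would not hold as given.

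Self-to-self arrays gave the background of the method. On the 3 arrays, 109 of 11693 probes passed limma's test for Cy5 against Cy3, 0 of them higher in Cy5, and 12 were at least 2-fold apart. This count was unstable, at 403 to 1438 with 1 array left out and 847 with robust moderation. After centring each array the count was 0, with 1855 probes at an unadjusted p under 0.05. The SD of centred ratios was 0.247 to 0.349 on the log2 scale, and 95% of the probes' means over the 3 arrays lay within 0.392 of 0. The self-to-self arrays had no dye swap, so dye bias remains in them.

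**Figure D4:**
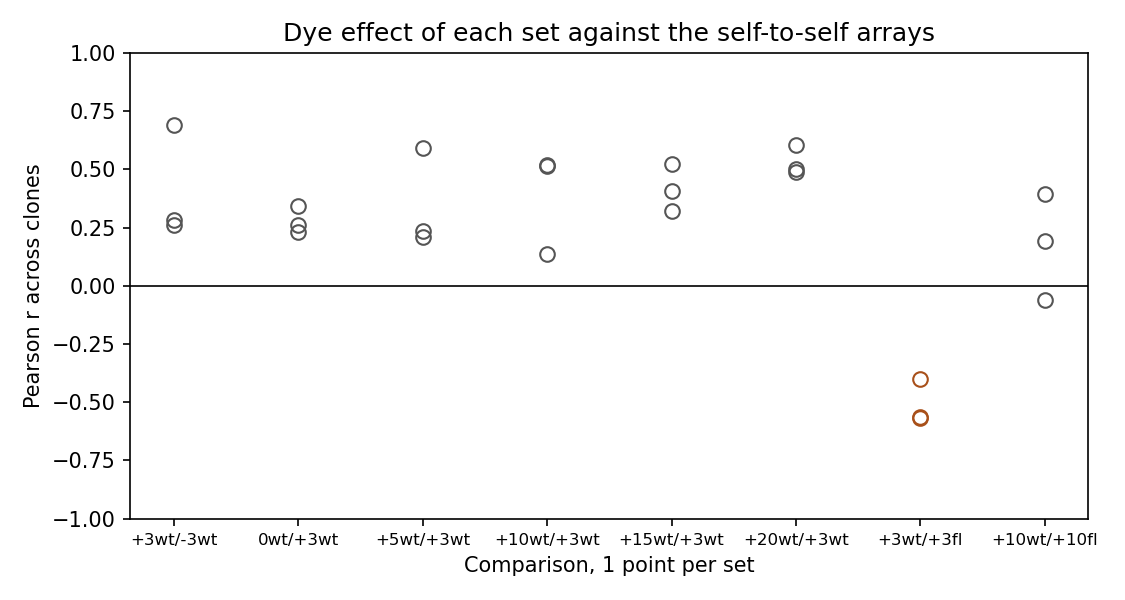
Pearson r across clones (y axis) between the dye effect of each set as deposited and the mean of the self-to-self arrays, by comparison (x axis), 1 point per set. The 3 sets of wild type against fl at +3 lie between -0.57 and -0.40, and the other 21 sets between -0.06 and 0.69.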

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

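The tests of the sign at +3, of the shared array, of lower clones relative to the median of their plates and of other splits of the sets were chosen after the results had been seen, and the other tests of array plates before, although the plates' share of the variance and the shares by plate had been seen.

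The clone values of wild type against fl at +3, as deposited, ran against the other comparisons, with a Pearson r across clones of -0.66 with wild type against fl at +10. A true opposite change at +3 alone would leave the dye effect of these arrays as it is on the others, but its highest correlation with the self-to-self arrays over the 3 sets was -0.40. Clone rows exchanged between forward and swapped array within each set would turn the dye effect and keep the sign of the RNA difference. Such an exchange was not tested, so a true opposite change together with it is not excluded. An exchange of RNAs or dye labels on the 6 arrays would also keep the dye effect, whose highest correlation with that of the other comparisons was -0.47. A candidate explanation is that the clone rows were deposited as fl over wild type, which requires a negative dye correlation in each set, and its mean was -0.51. The direction of all ratios, which the labels do not state, stays open.

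An array of +5 against +3 and an array of +10 against +3 share 19 of 19 control values to 6 decimals. Separate arrays of similar RNA are argued against by the other pairs of arrays, which share at most 1 such value. A candidate explanation is one scan deposited under both comparisons, which requires most of these values to be equal, and 19 of 19 were. Across clones, the version under +10 correlated at 0.740 to 0.825 with the other +10 arrays and at 0.575 to 0.710 with the other +5 arrays, while the ranges of the version under +5 overlapped, at 0.757 to 0.845 and 0.582 to 0.763. The values lean towards +10, but the age to which the scan belongs stays open and no biological explanation was tested.

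By the plates in the clone names, 332 of 5897 tested clones (5.63%) on plates below 80 and 35 of 2925 (1.20%) on plates from 80 up were at least 2-fold higher in wild type at both ages, a division chosen after seeing the shares. By a cut-off set before the test, an offset of whole plates would need a median at least 1 lower from plate 80 up. At +10 the medians were -0.33 and -0.0092, a difference of -0.32, which fell short of it. The cut-off was a choice, and an offset of that smaller size would also lower the share past 2-fold. At +3 the medians were -0.087 from plate 80 up and -0.059 on the others, so a gap of that size was not seen there. An offset of that size at +10 therefore stays open as a part of the pattern. Weaker or failed spots would thin out both directions, and the share at least 2-fold lower in wild type was 1.55 times that of the other plates, but the lower median by itself raises this share, which was 0.581 times when taken from the median of the own plates. Weaker or failed spots therefore stay open, with 27.3% of clones from plate 80 up untested at +10 against 17.8% on the others. Which libraries or tissues the plates came from is not given in the sources used here, so a difference in clone content stays open as a hypothesis and no biological explanation was tested.

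Measured clones, medians and SDs per array were examined for arrays standing apart in groups of 6, 24 tests in all, of which chance would mark about 1 in 20. The shared array in +10 against +3, set 2 forward, had a median of -0.19. In +15 against +3, the set 3 forward array had a median of -0.014. In +20 against +3, the set 2 dye swap measured 9593 clones, and in wild type against fl at +3 the set 2 forward array measured 8435.

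The genotype difference changed between +3 and +10 for 3975 probes by limma's test of the difference itself. It changed by 4.37 for CM025C03, by 4.29 for CM027E10, by -3.12 for CM099E09 and by -2.81 for CM101H12. With the deposited sign at +3 these are 0.47, 1.61, 4.88 and 0.68, so they rest on the turned sign.

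Control spots named Y5 to Y8, outside the main measurement, differed between the RNAs far beyond their self-to-self range, and the amounts added are not given. The mean log2 ratio of Y5 was -3.91 for wild type over fl at +3, against -0.20 to 0.49 on self-to-self arrays. Y6 stood at -4.60 for wild type over fl at +10 (self-to-self -0.11 to 0.19), Y7 at 2.80 for +15 over +3 (self-to-self -0.13 to 0.49) and Y8 at -2.84 for wild type over fl at +10 (self-to-self -0.18 to -0.03). Y5 and Y6 were 2.52 and -4.10 for +5 over +3, with the same signs at +10, +15 and +20, and -2.84 and 3.29 for +3 over -3, so that +3 lay on one side. For 0 over +3 they were -3.31 and 4.11, which puts +3 on the other side. For wild type over fl they were -3.91 and 2.71 at +3 and 1.70 and -4.60 at +10, opposite in sign, without any turning of control values. The comparison at +10 holds no +3 RNA, so this opposition is not a conflict by itself. Against fl, +3 wild type lay on the side it had against -3, +5, +10, +15 and +20. Whether the added amounts or the direction of the control values differed at 0 stays open. Being control values, these spots do not settle the sign of the clone rows at +3.

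Other splits of the sets were too few for a share under 0.05, since 3 sets allow 4 sign patterns and 3 against 3 allow 10 splits. In each of the 9 contrasts examined, 1 split, the real one, gave as many changed probes. The real count and the highest other were 4824 and 714 at -3, 3342 and 0 at 0, 7273 and 217 at +15, and 7272 and 162 at +20, each against +3. They were 4476 and 120 for wild type against fl at +3, 6092 and 404 at +10, and 3975 and 47 for the change of that difference. From -3 to 0 they were 2051 and 0, and from +15 to +20 they were 817 and 0.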

How the results depend on the processing

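Keeping exact zeros, keeping the shared array and the deposited sign at +3 were tried after seeing the data. Under the alternatives, 279 counts stayed within 1.5 times the value reported and 76 did not. The cause of these moves was not tested, except where fewer arrays or a stricter threshold entered. No brightness is in the table used here and clones carry no annotation, so the filter on dim spots and the gene list alternatives were not run, and signal over background cannot be judged. Centring called 963 probes from +5 to +10 and 0 in self-to-self. Scaling called 6770 at 0, 3705 from -3 to 0 and 450 from +15 to +20. Between +5 and +10, a dye term called 1084, a random block 1006, either array of a set 1052 and the contrast fitted alone 185. The 0 comparison fitted alone called 6446. Forward arrays alone called 1515 at 0, 2251 for the change of the genotype difference, 1169 from -3 to 0, 85 from +5 to +10, 1401 from +10 to +15 and 271 from +15 to +20. Swapped arrays alone called 426 from +15 to +20. With adjusted p under 0.01 the counts were 2101 at 0, 2010 for fl, 995 from -3 to 0, 198 from +5 to +10, 1888 from +10 to +15, 371 from +15 to +20 and 0 in self-to-self. With at least 2-fold they were 679 at -3, 383 at 0, 749 at +5, 1024 at +10, 1624 at +15, 1593 at +20, 502 and 1242 for wild type against fl at +3 and +10, 640 for their difference, 895 for fl, 209, 137, 703 and 122 for the neighbouring ages in order, 4097 over ages, 326 and 369 for the overlaps with +10 over +3 and between +3 and +10, and 12 in self-to-self. The one-sample test, run on the direct comparisons without shared spread, gave 0 at -3, 2123 at 0, 0 at +5, 0 at +10, 2916 at +15, 4093 at +20, 5 and 2702 for wild type against fl at +3 and +10, and 0 and 2 for the overlaps. At an unadjusted p under 0.05 this test gave 2038 at -3, 1799 at +5 and 2534 at +10. Robust moderation called 847 in self-to-self.

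With each set left out in turn, counts ran from 3077 to 4613 at -3, 2026 to 2201 at 0, 2445 to 3022 for the change of the genotype difference, 1320 to 2551 for fl, 902 to 2010 from -3 to 0, 171 to 255 from +5 to +10, 1617 to 2573 from +10 to +15, 292 to 420 from +15 to +20, 5511 to 6869 over ages and 403 to 1438 in self-to-self. A comparison left with 1 set was assumed to vary like the others. With the deposited sign at +3, values of wild type minus fl there became -4.28 for CM005F03, -4.00 for CM099E09, 2.21 for CM024F10 and 2.06 for CM032E03, the median of the 878 probes became -0.91, the change to +10 became 4.88 for CM099E09 and 0.68 for CM101H12, and 275 probes were higher at both ages. Of 51 named values, 35 lost their call under some alternative, 33 under the one-sample test, 1 with forward arrays alone and 1 with the deposited sign.

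By the rule that every pair should exceed 0.1, set numbers did not pair the samples. Deviations of same-numbered sets in different comparisons correlated at -0.25 to 0.33 with a median of 0.05, and 17 of 70 pairs exceeded 0.1. In different-numbered sets they correlated at -0.30 to 0.27 with a median of -0.02, and 13 of 141 exceeded 0.1, so a weak shared part is not excluded. With set number as a fixed replicate block the counts were 6130 and 4552 for wild type against fl at +10 and +3, 4097 for their difference, 4932, 3364, 5545, 6040, 7347 and 7296 at the ages in order, and none moved by over 1.5 times.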

Other observations

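Single clones combined age and genotype differences in ways the comparisons taken alone do not show. Clone CM099E09 was at its highest at +3 among the wild-type ages measured, at -3.13 at -3, -0.57 at 0, -2.72 at +5 and -5.66 at +20 against +3, and it was 16.0-fold higher in wild type than in fl at +3. With all ratios turned, +3 is its lowest age, and with the deposited sign its wild-type value at +3 is -4.00 against fl. Clone CM086E04 was 2.78 higher in wild type than in fl at +10. Against +3 in wild type it was at -1.41 at +5, -1.89 at +10 and -6.50 at +15. Clone CM050F11, lower in wild type than in fl at +10, was at -0.02 at +5 and at 2.39 at +20 in wild type. Clones CM005H11 and CM025A04, the largest decreases at 0, were higher in wild type than in fl by 4.56 and 4.29 at +10. Clones and profiles were chosen here after their values were seen.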
